A study of Homo sapiens with 4 samples.

How the data were processed

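RNA of 4 samples was measured by sequencing, 2 of the human iPSC line 253G1 and 2 of MSC derived from it. Per the labels' protocols, MSC were made from iPSC grown in a differentiation medium with bFGF (10 ng/mL), the TGF-beta receptor inhibitor SB431542 (4 µM) and the WNT agonist CHIR99021 (4 µM), changed daily for 5 days, and the resulting neural crest cells were plated on day 6 in a medium with 10% fetal bovine serum and moved to gelatin after 3 passages. RNA was extracted with TRIzol, depleted of ribosomal RNA, made into libraries with a NEBNext Ultra II kit and sequenced on a NextSeq 500, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

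The read trimmer Trim Galore, the aligner STAR and genome build hg19 are named, per the submitters' processing notes. Their versions and settings are not given in the sources used here. The gene annotation release is not given in the sources used here. The deposited expected counts per gene, which need not be whole because reads mapping to several genes are shared among them, have the column names of RSEM gene results, per the file headers. The same deposited files give TPM and FPKM per gene, per the file headers, and TPM sums to 1000000 or 999999 over all 60662 genes listed, ribosomal and small RNA genes included. Gene IDs are versioned Ensembl IDs, and symbols were added from a table of gene names that held 60402 of them (99.6%). Only 68.0% of IDs had the same version in GENCODE release 29, the annotation at hand, which is on another build, so no coordinates are given. The 45 entries for the Y copies of pseudoautosomal genes were left as deposited and are not reported. Strand handling is not given in the sources used here, so overlapping and antisense genes, paralogs and pseudogenes may share counts.

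Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr at its default settings (minimum count 10), which left 14385 and removed 46277. The filter works on raw library totals, and most counts of iPSC replicate 2 were ribosomal. A gene present in iPSC alone therefore needed a higher scaled level than one present in MSC alone. COL10A1 was left out at 9.72 and 3.33 CPM scaled by TMM in iPSC replicates 1 and 2. CD34 was tested at 2.34 and 1.97 in MSC replicates 1 and 2. Libraries were scaled by TMM, with factors of 1.75 and 0.312 for iPSC replicates 1 and 2 and 1.40 and 1.31 for MSC replicates 1 and 2. The groups were compared with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.0439, a coefficient of variation of 20.9%. Levels are given as CPM scaled by TMM, because the ribosomal share of iPSC replicate 2 moves deposited TPM. Errors of levels are SD over 2 libraries. Errors of log2 fold changes are approximate SE, taken as the size of the fitted change over the square root of its F statistic. Folds against a group with no count use a floor of 3 counts over that group, and genes with 1 to 3 counts in a group are given as a ratio with an exact 95% interval; both cover counting error only. Replicates were not duplicates: chi-square per degree of freedom was 367 between the iPSC libraries and 122 between the MSC libraries.

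Before the data were examined, 31 gene lists were fixed from textbook knowledge, along with the rule for named genes: the 12 largest increases and 12 largest decreases among called genes with mean TPM of at least 20 in the higher group and one direction in every pair of samples, the first 4 members of each list, the 2 largest called changes among the other members with mean TPM of at least 5, and the 5 genes of highest mean TPM per group. Mitochondrial, small RNA, unnamed and sex-linked marker genes were left out of the first part, and some genes that the rule picks are not reported here. KRT8, KRT18, KRT19, NGFR, POLR3G, SNAI1, TCF4, THBS4 and COL14A1, named as exceptions in their lists, fall outside the rule and were chosen after their values were seen. Lists with at least 5 tested genes went into camera with a preset correlation of 0.01, and into camera with an estimated correlation and fry. The alternatives were DESeq2's size factors, upper-quartile scaling, library totals, no filter, a filter of 50 counts, the replicate number as a block, each library left out, the 20 most abundant genes left out, ribosomal, mitochondrial and small RNA left out, limma-trend on log2 TPM and FPKM, limma voom, DESeq2's Wald test and stricter thresholds. Thinning all libraries to the shallowest was added after seeing the data. For it, ribosomal, mitochondrial and small RNA genes were left out first, and each library was cut to 629446 counts.

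The tests were tried on simulated data. Counts were simulated for MSC against iPSC with 200 changed genes, and 14275 genes then passed the filter. Of the changed genes that passed it, 12 of 65 changed 2-fold were recovered in the right direction, 56 of 64 changed 4-fold and 66 of 66 changed 16-fold. Among the calls, 3.6% were unchanged genes. The simulation gave all libraries the common dispersion of 0.0439 and left most genes unchanged. In the data 57.5% of genes were called. Replicates differed by a median of 0.48 log2 units in iPSC and 0.13 in MSC. The simulated error rate therefore need not hold for the data. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.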

Results

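RNA was sequenced from 253G1, a human induced pluripotent stem cell (iPSC) line, and from mesenchymal stromal cells (MSC) derived from it through a neural crest stage. There were 2 iPSC libraries and 2 MSC libraries, and the replicates of each group were numbered 1 and 2. Total expected counts were 4227689 in iPSC replicate 1, 3865461 in iPSC replicate 2, 116320269 in MSC replicate 1 and 5855895 in MSC replicate 2. Ribosomal RNA and rDNA entries took 69.41% of the counts of iPSC replicate 2, against 3.78% in iPSC replicate 1, 1.13% in MSC replicate 1 and 7.46% in MSC replicate 2. Nuclear protein-coding genes held 3426916 counts in iPSC replicate 1, 569601 in iPSC replicate 2, 102555289 in MSC replicate 1 and 4756623 in MSC replicate 2. A floor of 3 counts equalled 2.5 CPM (counts per 1000000 scaled counts) in iPSC replicate 2. The same floor was 0.416 CPM in iPSC replicate 1, 0.0186 in MSC replicate 1 and 0.393 in MSC replicate 2. Across genes, log2(CPM + 1) correlated at 0.92 between the iPSC replicates and at 0.989 between the MSC replicates (Pearson), while correlations between groups lay between 0.567 and 0.638. The most abundant deposited TPM values in iPSC belonged to ribosomal DNA entries, with means of 93400 for the unnamed genes ENSG00000280614 and ENSG00000281181, 93166 for ENSG00000280800, and 40426 for RNA5-8SN3 and a 5.8S rRNA entry. In MSC they belonged to RN7SL2 (72095), RN7SL1 (54058), RN7SK (35572), RMRP (32338) and ENSG00000280614 (20601). The iPSC means were carried by replicate 2, where ENSG00000280614 had 169582 against 17219 in replicate 1, and in iPSC replicate 1 RN7SL2 (39834), RN7SL1 (25958) and RMRP (23566) lay above it. The ribosomal entries and the RN7SL and RN7SK genes have near-identical copies, so their values are uncertain.

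The comparison of MSC with iPSC asked which transcripts distinguished the derived stromal cells from the line they came from. Of the tested members of the gene lists, 29 of 33 mesenchymal transition, 30 of 44 matrix assembly and all 33 HOX genes were higher in MSC, and 29 of 30 pluripotency, 27 of 33 epithelial and 33 of 36 cell cycle genes were lower. These 6 lists passed the list test camera with a preset correlation but not with an estimated one (adjusted p = 0.47 for each). FGF5 (ENSG00000138675.16), a fibroblast growth factor gene, had no count in either iPSC library and 93.1 ± 14 scaled CPM in MSC (SD, n = 2), at least 261-fold higher against a floor of 3 counts over the iPSC group. VIM (ENSG00000026025.16), the intermediate filament gene of mesenchymal cells, rose from 35.9 ± 31.6 to 2230 ± 3.34 CPM (log2 fold change 6.05 ± 0.81, SE). MYCN (ENSG00000134323.12), a proto-oncogene transcription factor, fell from 52.9 ± 26.5 to 0.471 ± 0.631 CPM (log2 fold change -9.40 ± 1.19). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4256 of 14385 genes rose and 4012 fell, of which 3419 and 3281 changed by a log2 fold of at least 1. Without iPSC replicate 2, whose counts were mostly ribosomal, 7603 genes rose and 6017 fell. With TMM scaling 51.5% of the calls were higher, and with library totals alone 76.5% were (316 higher, 97 lower). Library totals ended the calls of 99 of the 162 genes that the rule for named genes picks. Of these 99, 87 kept at least 75% of their log2 fold change.

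The other largest increases named by the fixed rule were genes with no iPSC count. HOXA10 was at least 88.9-fold higher, HOXD10 at least 81.7-fold, HOXD11 at least 71.9-fold and HOXC10 at least 62.1-fold. C5orf46 was at least 48.9-fold higher, LINC00973 at least 34.8-fold and COPZ2, a coatomer subunit gene, at least 32.7-fold. MT1L (at least 64.5-fold), COMMD3 (at least 32.3-fold) and KRTAP2-3 (at least 27.9-fold) belong to families with near-identical members or overlap a neighbouring gene, so their counts are uncertain. Among the largest decreases, ZFP42, a marker of undifferentiated cells, fell from 47.9 ± 7.78 to 0.508 ± 0.579 CPM (log2 fold change -8.23 ± 0.76), and APELA, which encodes a peptide hormone of pluripotent cells, from 32.3 ± 7.96 to 0.374 ± 0.398 CPM. The fibrillin gene FBN3 (-8.34), CAMKV (-8.52), the chemerin gene RARRES2 (-8.72) and the noncoding HPAT5 (-8.73), LNCPRESS1 (-8.60) and LINC00698 (-8.55) fell by similar log2 amounts. CRABP1, a retinoic acid binding protein gene, had 3 counts in MSC and an MSC to iPSC ratio of 0.00121 (95% counting interval 0.000246 to 0.00362), pooled over MSC libraries that differed (0.00619 CPM in replicate 1 and 0.262 in replicate 2, against 14.8 in iPSC). RPS3AP34 (-8.28) is a processed pseudogene and may share reads with its parent gene, so its count is uncertain. The size of these decreases depended on the MSC library: for the 10 named in this paragraph and MYCN, log2 fold changes lay between -5.63 and -4.65 without MSC replicate 1 and between -10.56 and -8.03 without MSC replicate 2. HPAT5, LINC00698 and RPS3AP34 were at -4.90, -4.76 and -4.65 without MSC replicate 1 and at -9.55, -9.29 and -8.80 without MSC replicate 2. Without iPSC replicate 1, the decreases of HPAT5, LINC00698 and RPS3AP34 no longer passed (adjusted p = 0.05, 0.069 and 0.11 in the same edgeR test, where all 4 libraries gave 0.0012, 0.0016 and 0.002).

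Pluripotency genes fell almost as a block. Of 30 tested members of the pluripotency list, 29 fell and 1, POLR3G, rose, with the same counts adjusted over the list alone and a median log2 fold change of -5.79. LIN28A, an RNA-binding protein gene that blocks let-7 maturation, went from 892 ± 208 to 17 ± 20.9 CPM (log2 fold change -5.79 ± 1.29), POU5F1, which encodes OCT4, from 404 ± 88.5 to 21.3 ± 8.83, and NANOG from 96.3 ± 43.9 to 2.95 ± 3.42. TERT, the telomerase catalytic subunit gene, had a log2 fold change of -8.49, and of -4.91 without MSC replicate 1. The list passed camera (adjusted p = 1.9e-07) but not with an estimated correlation (adjusted p = 0.47 with an estimated correlation). The MSC replicates differed, with LIN28A at 2.24 CPM in replicate 1 and 31.9 in replicate 2, and the list's median was -4.29 without MSC replicate 1 and -7.59 without MSC replicate 2. POU5F1 and NANOG have pseudogenes of near-identical sequence, so part of their counts is uncertain. Epithelial genes moved the same way, with 27 of 33 tested members lower, 4 higher and 2 not past the test (27 lower and 5 higher adjusted over the list alone). CDH1, the E-cadherin gene, fell from 186 ± 46.3 to 3.38 ± 3.93 CPM, and EPCAM from 127 ± 12.8 to 3.71 ± 2.35. CDH1 lay at 0.6 CPM in MSC replicate 1 and 6.16 in MSC replicate 2. The epithelial median of -4.56 became -3.47 without MSC replicate 1 and -4.6 without MSC replicate 2. Of the 4 that rose, 3 were the simple-epithelium keratin genes KRT8 (log2 fold change 1.56), KRT18 (1.25) and KRT19 (1.00). Keratin pseudogenes could share reads with KRT8 and KRT18. Camera gave adjusted p = 3.4e-06 for the list, and adjusted p = 0.47 with an estimated correlation.

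Mesenchymal genes rose. Of 33 tested members of the mesenchymal transition list, 29 were higher, 1 (TCF4) lower and 3 not called (30 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 5.12. The zinc finger transcription factor gene ZEB1 rose from 0.624 ± 0.294 to 46.2 ± 5.41 CPM, the BMP antagonist gene GREM1 from 4.09 ± 4.81 to 1120 ± 66.1 and FN1, the fibronectin gene, from 302 ± 228 to 14800 ± 1120. SNAI1, with a log2 fold change of -0.29, was not called. Camera gave adjusted p = 9.1e-15, and adjusted p = 0.47 with an estimated correlation. Of 20 tested MSC surface markers, 17 rose, 2 fell and 1 was not called, and the counts were equal adjusted over the list alone (camera adjusted p = 2.4e-07, and adjusted p = 0.47 with an estimated correlation). NT5E, which encodes CD73, rose from 3.61 ± 4.31 to 349 ± 31.4 CPM, ENG, which encodes CD105, from 3.54 ± 0.881 to 61.4 ± 4.77, and CD44 from 8.05 ± 5.1 to 732 ± 68.5. THY1, which encodes CD90, was lower at 75.8 ± 4.71 against 174 ± 87 CPM (log2 fold change -1.17 ± 0.36, adjusted p = 0.035 in edgeR's test). That call ended without iPSC replicate 2 (-0.06, adjusted p = 0.65 in edgeR's test), MSC replicate 1 (-0.91, adjusted p = 0.14) or MSC replicate 2 (-0.90, adjusted p = 0.13), and the direction turned with limma-trend on log2(TPM + 1) (0.57). NGFR, a neural crest receptor gene, fell by 4.02 on the log2 scale. Of the MSC exclusion markers, which are blood cell antigens, 2 of 10 were tested, and 1 rose and 1 fell, as also adjusted over the list alone. CD74 fell from 22.2 ± 9.8 to 2.36 ± 0.556 CPM, and CD34 lay at 2.15 ± 0.263 CPM in MSC with 3 iPSC counts, a ratio of 6.51 (interval 2.21 to 31.7). The CD34 call was lost without iPSC replicate 1 (adjusted p = 0.061 in edgeR's test) or MSC replicate 1 (0.081). The fitted log2 fold change of 2.65 was 2.70 without MSC replicate 1. Without iPSC replicate 1 no iPSC count of CD34 remained. The floor of 3 counts in iPSC replicate 2 (2.5 CPM) lay above the MSC level, so no fold could be measured there.

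**Figure D1:**
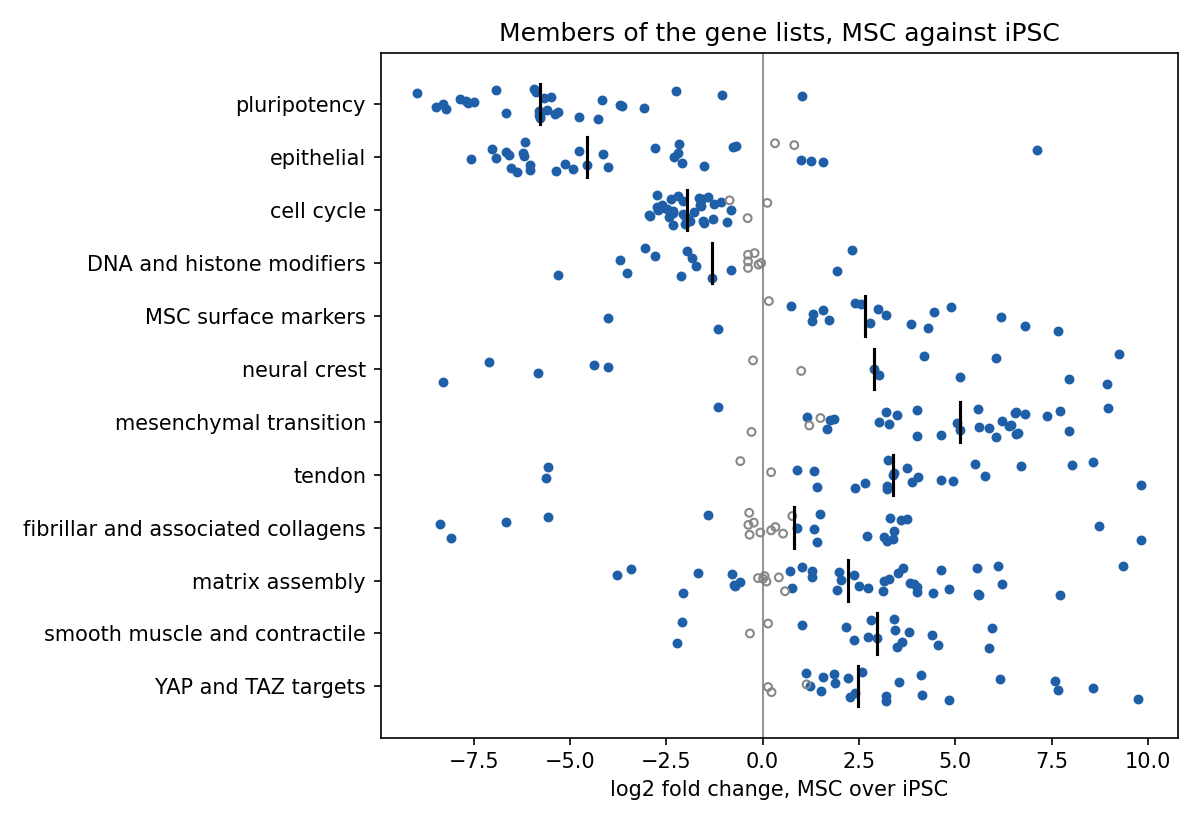
Log2 fold change of MSC over iPSC (x axis) for each tested member of 12 gene lists (y axis), with filled points for genes past adjusted p 0.05, open points for the rest, a black line at each list's median, and genes with no iPSC count drawn at their lower bound. Pluripotency members centre at -5.79 and mesenchymal transition members at 5.12.

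Of 15 tested neural crest genes 8 were higher, 5 lower and 2 not called, unchanged adjusted over the list alone (median log2 fold change 2.90, camera adjusted p = 0.053, and adjusted p = 0.52 with an estimated correlation). With 1 library left out in turn the camera adjusted p ran from 0.03 to 0.17, and it was 0.04 with upper-quartile scaling. TFAP2A, an early crest transcription factor gene, reached 60.9 ± 5.46 CPM in MSC with 1 iPSC count (ratio 541, interval 97.1 to 21400), and NR2F2 reached 237 ± 4.37 CPM (ratio 672, interval 230 to 3260). Both ratios pool the iPSC libraries. The iPSC counts of both genes were all in replicate 2 (0.832 CPM for TFAP2A and 2.5 for NR2F2), against which the folds were smaller. FOXD3, which is also a member of the pluripotency list, fell from 11.4 ± 1.97 to 0.0186 ± 0.0262 CPM. SOX10 lay at 4.23 ± 0.1 CPM in iPSC and 0.672 ± 0.347 in MSC but was below the filter, so its difference was not tested. PAX3 (no iPSC count, 0.134 ± 0.00354 CPM in MSC) was also below the filter, and TFAP2B had no count in any library. All 33 tested HOX genes rose, also when adjusted over the list alone, and 27 of them had no iPSC count. The median log2 fold change was 11.42 as fitted and 4.83 with those 27 at their lower bounds (camera adjusted p = 9.1e-15, and adjusted p = 0.47 with an estimated correlation). HOXA10 reached 31.7 ± 2.05 CPM and HOXD10 29.2 ± 1.55, while HOXA2 lay at 2.40 ± 0.617.

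**Figure D2:**
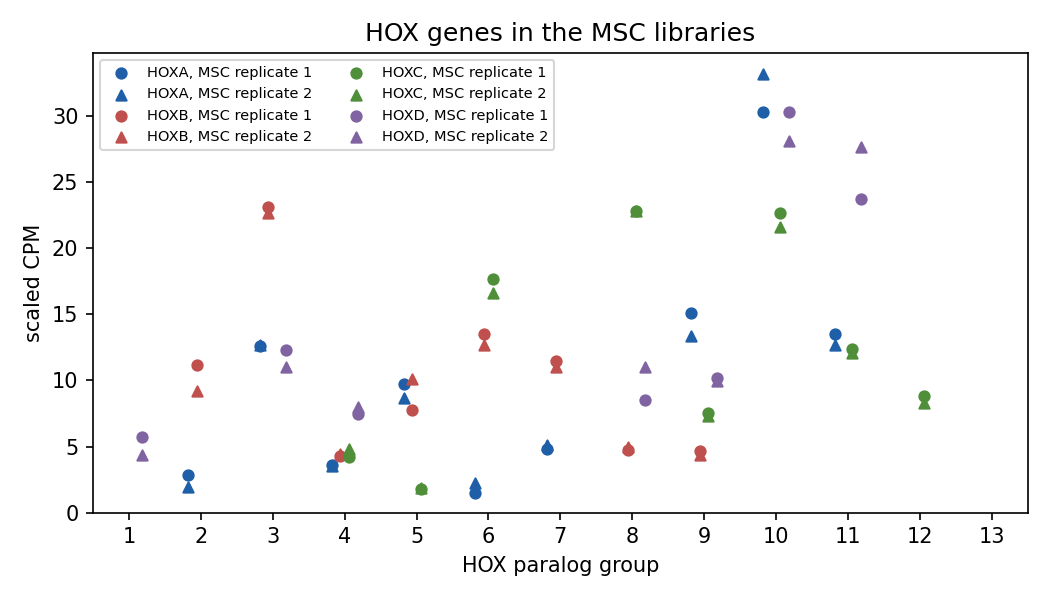
Scaled CPM (y axis) of 32 of the 33 tested HOX genes in MSC replicate 1 (circles) and MSC replicate 2 (triangles) by paralog group (x axis), coloured by cluster. HOXA10 (31.7 CPM on average) and HOXD10 (29.2) have the highest levels, and no gene of paralog group 13 was tested.

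Of 25 tested tendon genes 21 were higher, 2 lower and 2 not called, equal adjusted over the list alone (median log2 fold change 3.40, or 3.38 with 4 genes at their bounds, camera adjusted p = 4.1e-09, and adjusted p = 0.47 with an estimated correlation). MKX, a tendon homeobox transcription factor gene, lay at 3.37 ± 0.43 CPM in MSC with 3 iPSC counts (ratio 8.66, interval 2.95 to 42.1). The early growth response gene EGR1 rose from 9.29 ± 6.86 to 36.3 ± 1.16 CPM, and GDF5 was at least 45.9-fold higher. SCX, the scleraxis gene, was below the filter at 2.71 ± 0.882 CPM in iPSC and 1.18 ± 0.368 in MSC, as was TNMD, the tenomodulin gene (0.139 ± 0.196 and 0.00309 ± 0.00437). THBS4 and COL14A1, matrix genes of tendon, fell by 5.62 and 5.58 on the log2 scale. Of 28 collagen genes, 14 rose, 5 fell and 9 were not called, equal adjusted over the list alone (median 0.83, camera adjusted p = 0.0065, and adjusted p = 0.47 with an estimated correlation). With 1 library left out in turn the collagen median ran from 0.72 to 1.49, and without iPSC replicate 2 the list's camera adjusted p was 0.18. COL3A1 reached 230 ± 1.26 CPM with 2 iPSC counts (ratio 968, interval 268 to 7990), and COL8A1 rose from 3.05 ± 2.75 to 827 ± 54.7. The COL3A1 ratio pools the iPSC libraries, and both counts were in iPSC replicate 2 (1.66 CPM), against which the fold was smaller. COL1A1, the main collagen chain of tendon and bone, was already at 1010 ± 509 CPM in iPSC and rose to 2680 ± 84.2 (log2 fold change 1.40 ± 0.47, adjusted p = 0.047 in edgeR's test). The COL1A1 call was lost without MSC replicate 1 or 2, where its log2 fold change was larger (1.68 and 1.78, adjusted p = 0.18 and 0.16 in edgeR's test), and with the replicate block (0.053), upper-quartile scaling (0.068), the 50-count filter (0.088), library totals (0.84) and limma-trend (0.68 to 0.9). The cartilage collagen genes COL2A1 and COL9A1 fell by 8.09 and 8.37 on the log2 scale, and without MSC replicate 1 they were at -6.07 and -4.30. COL2A1 was at -6.56 without iPSC replicate 1 and COL9A1 at -9.91 without MSC replicate 2. The COL9A1 call was lost without iPSC replicate 1 (-5.66, adjusted p = 0.068 in edgeR's test). Of 44 matrix assembly genes 30 rose, 8 fell and 6 were not called, equal adjusted over the list alone (median 2.21, camera adjusted p = 3.8e-08, and adjusted p = 0.47 with an estimated correlation). LOX, the collagen crosslinking enzyme gene, rose from 2.01 ± 0.686 to 359 ± 29.8 CPM and the fibrillin gene FBN1 from 30.7 ± 19 to 2150 ± 77.7, while the proteoglycan gene VCAN fell from 1160 ± 75.1 to 280 ± 0.611. The VCAN call was lost without MSC replicate 1 or 2 (adjusted p = 0.081 and 0.13 in edgeR's test), though its log2 fold change of -2.06 stayed at -1.83 and -1.68.

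Lists of other lineages were smaller, and the filter was stricter for genes present in iPSC alone. Of 7 osteoblast genes 6 rose, among them RUNX2 (2.98 ± 1.87 to 33.5 ± 6.4 CPM), and 1 fell, the alkaline phosphatase gene ALPL (59.7 ± 16.8 to 1.65 ± 1.19), as also adjusted over the list alone (camera adjusted p = 0.053, 0.04 with upper-quartile scaling and 0.18 to 0.37 with 1 library left out in turn). Of 11 chondrocyte genes 5 rose, 4 fell and 2 were not called (camera adjusted p = 0.27, fry adjusted p = 0.049), with a median of 1.00, a mean of -0.66 and the test's direction up. SOX9, a cartilage transcription factor gene, rose from 6.87 ± 2.06 to 49.2 ± 1.96 CPM. Of 7 adipocyte genes 4 rose and 3 fell (camera adjusted p = 0.73, direction down against a median of 1.91 and a mean of 1.65). FABP4, with no iPSC count, was at least 5.48-fold higher against a floor over both iPSC libraries. Its call was lost without iPSC replicate 1. There the floor of 2.5 CPM in iPSC replicate 2 lay above the 1.96 ± 0.386 CPM in MSC, so no fold could be bounded. Without iPSC replicate 2 both medians turned negative (-1.29 for chondrocyte and -1.34 for adipocyte genes), as they did without MSC replicate 2 (-1.07 and -1.24), and the chondrocyte median did without MSC replicate 1 (-1.03). Smooth muscle and contractile genes rose in 15 of 19 cases, fell in 2 and were not called in 2 (camera adjusted p = 2.6e-06, and adjusted p = 0.47 with an estimated correlation), with ACTA2, the smooth muscle actin gene, going from 3.54 ± 3.24 to 123 ± 3.05 CPM and MYOCD from 2.29 ± 0.884 to 165 ± 13.9. The counts of these 4 lists adjusted over the list alone were the same. Of 8 neural and neuronal genes 3 rose (4 adjusted over the list alone), 4 fell (4) and 1 was not called (camera adjusted p = 0.57). Their median was -0.16 with TMM, 0.18 with library totals and between -3.46 and -0.08 with 1 library left out in turn. Of 6 endothelial genes 1 rose, 3 fell and 2 were not called (camera adjusted p = 0.16, 0.046 without MSC replicate 1 and 0.049 with the replicate block, and fry adjusted p = 0.049), with the VEGF receptor gene KDR falling from 161 ± 68 to 3.92 ± 4.28 CPM. Too few genes were tested for camera in the skeletal muscle (2 of 12, both lower), Schwann cell and glia (4 of 10, 1 higher and 3 lower), melanocyte (3 of 7, 1 higher, 1 lower and 1 not called) and endoderm (2 of 12, both higher) lists. Adjusted over the list alone, these 5 lists, endothelial included, gave the same counts.

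Of 36 tested cell cycle genes 33 fell and 3 were not called, equal adjusted over the list alone (median log2 fold change -1.96, camera adjusted p = 4.1e-09, and adjusted p = 0.47 with an estimated correlation). The proliferation marker gene MKI67 fell from 383 ± 216 to 75.6 ± 2.69 CPM and the helicase subunit gene MCM5 from 128 ± 0.951 to 16.7 ± 2.1. Of 27 cell cycle inhibitors and secreted senescence genes 20 rose, 3 fell and 4 were not called, equal adjusted over the list alone (median 4.19, camera adjusted p = 1.3e-06, and adjusted p = 0.47 with an estimated correlation). CDKN1A, the p21 gene, rose from 52.3 ± 57.9 to 530 ± 7.11 CPM, its iPSC replicates lying at 11.4 and 93.2, and the interleukin gene IL6 rose from 1.04 ± 0.882 to 49.8 ± 6.61. Of 19 DNA and histone modifiers 11 fell, 2 rose and 6 were not called, equal adjusted over the list alone (camera adjusted p = 0.0021, and adjusted p = 0.47 with an estimated correlation), with DNMT3B falling from 592 ± 92.6 to 15.6 ± 12.6 CPM and JARID2 from 428 ± 57.5 to 33.1 ± 8.12.

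Of 24 TGF-beta genes 16 rose (17 adjusted over the list alone), 1 fell and 7 were not called (camera adjusted p = 3.3e-06, and adjusted p = 0.47 with an estimated correlation), with the TGF-beta ligand gene TGFB2 going from 1.87 ± 2.06 to 350 ± 34.4. Of 24 YAP and TAZ targets 21 rose, none fell and 3 were not called, equal adjusted over the list alone (camera adjusted p = 1.1e-08, and adjusted p = 0.47 with an estimated correlation), with CCN2 rising from 87.1 ± 48.6 to 2430 ± 78.7 CPM and ANKRD1 from 2.08 ± 2.94 to 598 ± 1.17. WNT pathway genes rose in 10 and fell in 8 of 20 cases, equal adjusted over the list alone (camera adjusted p = 0.041, and adjusted p = 0.47 with an estimated correlation), with WNT5A (log2 fold change 5.15) and DKK1 (7.62) higher and AXIN2 (-4.61) and ROR2 (-6.27) lower. The WNT list passed with none of the libraries left out in turn (camera adjusted p = 0.057 to 0.42), nor with DESeq2's size factors (0.051) or the replicate block (0.15). Its median was -0.01 after thinning, a setting added after the data were seen. Interferon and antigen presentation genes rose in 17 of 24 cases (18 adjusted over the list alone), fell in 2 and were not called in 5 (camera adjusted p = 0.00017, and adjusted p = 0.53 with an estimated correlation). B2M, the MHC class I light chain gene, rose from 25.5 ± 5.19 to 267 ± 4.82 CPM. Of 19 stress genes 11 rose, 2 fell and 6 were not called, equal adjusted over the list alone (camera adjusted p = 0.004, and adjusted p = 0.47 with an estimated correlation), with JUN going from 15.8 ± 10.6 to 118 ± 3.22 CPM. Glycolysis genes split into 7 higher, 6 lower and 11 not called of 24, equal adjusted over the list alone (camera adjusted p = 0.51), with LDHA, the lactate dehydrogenase A gene, rising from 61.3 ± 7.52 to 474 ± 18.1 CPM and the glucose transporter gene SLC2A3 falling from 585 ± 398 to 61 ± 18.3. Of 25 oxidative phosphorylation genes 4 rose and 21 were not called, and 0 passed edgeR's test adjusted over the list alone, with 5 at an unadjusted p under 0.05 (camera adjusted p = 0.51, and 0.027 without iPSC replicate 2). Of 19 imprinted genes 8 rose (9 adjusted over the list alone), 6 fell (7) and 5 were not called (camera adjusted p = 0.31), with IGF2 rising from 2.22 ± 2.75 to 161 ± 15.4 CPM and PLAGL1 from 1.04 ± 0.882 to 53.9 ± 2.99. IGF2 and PLAGL1 overlap other annotated genes, so their counts are uncertain.

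In all, 17 of 26 lists passed camera with the preset correlation and 0 passed with an estimated one, where adjusted p ran from 0.47 to 0.76 and 0 lists had an unadjusted p under 0.05. With fry, which tests each list on its own, 9 lists passed, 7 of the 17 and the chondrocyte and endothelial lists. In data simulated for this comparison, a list moved 4-fold as a whole missed the threshold with an estimated correlation (camera adjusted p = 0.067). That simulation drew each gene independently, whereas the estimated correlation in the data ran from -0.13 in the endothelial list to 0.95 in the HOX list. It therefore cannot tell why the lists missed the threshold in the data.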

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

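Thinning was chosen after seeing the data; the other alternatives were fixed before. The median log2 fold change over all genes was 0 with TMM and moved to -0.2 with upper-quartile scaling, 0.39 with library totals, 0.26 without the 20 most abundant genes, and 0.98, 1.3 and 0.57 with TPM + 1, TPM + 0.1 and FPKM + 1. Against 8268 genes changed (4256 higher, 4012 lower), library totals gave 413 (316, 97), limma-trend 9 (6, 3) with TPM + 1, 346 (321, 25) with TPM + 0.1 and 1024 (656, 368) with FPKM + 1. No filter gave 15524, 9252 of them lower. A threshold of 0.01 gave 2635 lower, and glmTreat 4461 (2292, 2169), fewer by construction. Leaving out ribosomal, mitochondrial and small RNA gave 10314 of 16227 genes tested. Thinning, which began with the same step, gave 5243 of 10436 tested, 2545 of them higher. Leaving out 1 library gave 6125 to 13620 genes changed and 3213 to 7603 higher, the lone sample being assumed to vary like the other group; the upper values came without iPSC replicate 2. No gene called both with all libraries under TMM and in another setting was called in the opposite direction. NDUFA4, not called with all libraries (-0.03), ran from -0.36 without iPSC replicate 1 to 0.76 without iPSC replicate 2, where it was called. THY1 turned to 0.57 and 0.58, PCNA to 0.6 and 0.64 and HK2 to 0.63 and 0.8 with TPM + 1 and TPM + 0.1, and PCNA to 0.05 and HK2 to 0.16 with FPKM + 1, none of them called there. The THY1 call was also lost without the 20 most abundant genes (adjusted p = 0.056), without ribosomal, mitochondrial and small RNA (0.051) and with DESeq2's Wald test (0.097), and the CD34 call with that test (0.061). Of 162 genes that the rule picks, 99 lost their calls with library totals, though 87 of the 99 kept at least 75% of their log2 fold change: POU5F1 had -4.02 against -4.28 (adjusted p = 0.16), CDH1 -5.28 against -6.39 (0.081), ENG 4.70 against 4.28 (0.13) and RUNX2 3.50 against 3.17 (0.34), while MKI67 went from -2.33 to -1.48 (0.89). With limma-trend on TPM + 1, TPM + 0.1 and FPKM + 1, calls were lost for 152, 107 and 62 of the genes without a turn in direction. The calls of THY1, PCNA and HK2 were lost in addition where their direction turned. Some calls were also lost without 1 library, and none were with limma voom. The causes were not tested.

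Of the lists, 17 passed camera, 0 with an estimated correlation and 9 with fry. The pluripotency, MSC surface, epithelial, mesenchymal and tendon lists had adjusted p = 0.47 with an estimated correlation, and the first 4 of them 0.052 with fry. With fry's test for change in either direction 25 of 26 lists passed, all but the HOX genes (0.082), with the neural crest and osteoblast lists at 0.043. The neural crest list passed with upper-quartile scaling (median 2.71) and the 50-count filter (3.83), and its median without 1 library ran from 2.13 to 3.44. With 1 library left out, medians also ran from 1.24 to 2.53 for WNT, 1.06 to 2.17 for stress, 0.33 to 0.78 for glycolysis, 0.16 to 0.76 for oxidative phosphorylation, 0.31 to 1.2 for imprinted genes and -1.34 to -0.72 for DNA and histone modifiers. Without a filter the glycolysis and oxidative phosphorylation lists passed (camera adjusted p = 0.0012 and 1.3e-06), and with library totals the collagen list did not (0.069). The iPSC replicate correlation of 0.92 became 0.872 with TPM and 0.953 over all genes with a count. With the replicate block, 7067 genes changed (3711 higher, 3356 lower); deviations of same-numbered samples correlated at 0.05, so the numbers were not taken as pairs. Depth limits iPSC replicate 2 most, with 569601 coding counts.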

Other observations

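All tests of explanations below, and the genes of the next paragraph, were chosen after the values were seen.

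Transcription factors outside the lists also separated the groups. MEIS1, a HOX cofactor gene, had no iPSC count and 27 and 22.8 scaled CPM in MSC replicates 1 and 2, at least 69.8-fold higher. The T-box gene TBX3 lay at 49.7 and 52.7 CPM in MSC and TBX18 at 16 and 14.9 (1 to 3 iPSC counts each, ratios of 419 with a counting interval of 75.2 to 16600 and of 44.7 with 15.3 to 217), the forkhead gene FOXD1 at 34.6 and 36.4 and RUNX1 at 61.8 and 55.8, each rising in edgeR's quasi-likelihood test (adjusted p = 0.00037, 0.0013, 0.00048 and 0.0005). The TBX18 ratio pools iPSC libraries that differed (0.139 CPM in replicate 1 and 1.66 in replicate 2).

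MSC replicate 2 held iPSC transcripts that MSC replicate 1 nearly lacked. Over 54 coding genes at 50 CPM or more in both iPSC libraries and below 1% of that level in MSC replicate 1, the share in MSC replicate 2 had a median of 3.71% and quartiles of 3.1% and 4.36%, an upper to lower ratio of 1.41. In MSC replicate 1 the median share was 0.382%, which the choice of genes held below 1%. Incomplete silencing of the listed pluripotency genes more than of other iPSC genes is argued against. Over the 23 list members at 20 CPM or more in both iPSC libraries, whatever their level in MSC replicate 1, the level in MSC replicate 2 minus that in MSC replicate 1 had a median of 3.36% of the iPSC level, 1.13 times that of 464 other genes below 20% of their iPSC level in MSC replicate 1 (1.23 times for the 20 members under the same limit). The excess of the 464 genes was less even, with quartiles of 1.83% and 4.23% and a ratio of 2.31. That is above the limit of 2 set, after the values were seen, for one share over the 54 genes. The 464 genes were themselves chosen as lower in MSC replicate 1 than in iPSC. The test therefore cannot decide on incomplete silencing of iPSC genes at large. An exchange of reads at one rate between libraries is argued against too. At the 3.61% at which counts of the 54 genes appeared in MSC replicate 2, that library would have passed 1167 counts of IGFBP5 to each iPSC library, where 15 and 66 were seen. Of all 476 genes at 200 CPM or more in both MSC libraries, 51 had fewer counts in iPSC replicate 1 than this rate needs, beyond Poisson counting error adjusted for the number of genes, and 139 did in iPSC replicate 2. The tests of silencing and exchange replaced earlier ones, seen first, whose genes were chosen by their levels in MSC replicate 1 or iPSC replicate 2 or which took MSC replicate 1 as the source. One share of iPSC cells or RNA in this library may account for the pattern, and the test does not separate cells that stayed undifferentiated from RNA carried over.

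In iPSC replicate 2, CDKN1A lay at 93.2 CPM against 11.4 in replicate 1, GDF15 at 90.7 against 5.27, VIM at 58.2 against 13.6 and IGFBP5 at 54.9 against 2.08. VIM and IGFBP5 need between 0.65 and 1.9 times the median share of MSC genes there. At most 5.26% of those genes lay below the level needed by more than Poisson counting error. A gene at 200 CPM in MSC would have few counts in iPSC replicate 2 at such a share, so few genes could lie below. The test therefore cannot decide whether a share of MSC cells or RNA accounts for VIM and IGFBP5. Such a share is argued against for CDKN1A and GDF15, which need at least 8.24 times the median share, with 100% of those genes below. The genes were split this way after a joint test of all 4 was seen. For choosing the MSC genes 2 limits (0.5% and 2% of the MSC level) were tried, the second after results with the first were seen. Median shares were 1.05% (quartiles 0.695% and 1.82%) and 1.87% (quartiles 1.09% and 2.37%), so the shares were uneven. Of 37 other p53 targets measured, 28 were higher in replicate 2, with a median log2 ratio of 0.51 at percentile 100 of 10000 random lists matched on expression, and at percentile 100 again after correction for GC content and length (0.55) or after 1.87% of the MSC level was taken off (0.43). Higher p53 target RNA in this one library is a hypothesis, which a single pair of libraries cannot tie to the line or its culture.

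COL1A1 stood at 1370 and 651 CPM and COL1A2 at 284 and 115 CPM in iPSC replicates 1 and 2, while COL3A1 was at 0 and 1.66. MSC material in the iPSC libraries is argued against as the whole cause. It would bring all abundant MSC transcripts, and the test took 467 genes at 200 CPM or more in both MSC libraries, collagens left out, whatever their iPSC level. COL1A1 needs 51.2% of its MSC level in iPSC replicate 1 and 24.3% in replicate 2, and 279 and 129 of the genes lay below those shares, beyond Poisson counting error adjusted for the number of genes. COL1A2 needs 15.1% and 6.13%, and 128 and 24 genes lay below, 3 of the 24 below 0.5 times the share needed in replicate 2, so a smaller part from MSC is not excluded there. The genes were split after their joint test was seen, and this test replaced earlier ones, seen first, on MSC genes chosen for low levels in an iPSC library. Reads shared with other fibrillar collagen genes are argued against for COL1A1, since the 7 measured together came to at most 21.5% of it. COL1A2, at a lower level, was not tested this way. No biological explanation was tested.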
